A study of Mus musculus with 12 samples.

How the data were processed

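The study profiled endothelial cells from mouse ear skin with Affymetrix whole-transcript arrays. Per the labels' protocols, cells carrying PECAM1 were enriched on antibody-coated beads and sorted on podoplanin, the Prox1-GFP reporter and LYVE1, RNA was extracted with a column kit for small samples, and 500 pg of total RNA per sample was amplified and labelled as sense-strand cDNA. An input this small needs strong amplification, which can add noise to weakly expressed genes. The labels call the 3 arrays of each group biological replicates but do not say whether each came from a single mouse or from a pool, and they give the age both as adult and as 5 weeks. All 12 arrays were used, in the 4 groups given by the labels, and no column was left out.

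The values analysed are log2 probe set values that the authors deposited after RMA, per the submitters' processing notes. RMA subtracts background, brings the arrays of a run to a common distribution and summarises the probes of a transcript cluster robustly, which compresses differences of weak signals and hides any change in total RNA per cell. The software and its version, the annotation and whether all arrays were normalized together are not given in the sources used here. The log2 scale was read from the values. Array medians lay between 6.06 and 6.17 without being identical. No detection flags were used here, so a fold change of a gene near the low end of the scale can be compressed. The platform's positive control rows lay above its negative control rows with an area under the curve of 0.861 to 0.897 per array. For arrays, the number of replicates and not a depth sets the precision: the median gene had an SD of 0.141 within groups, and the prior and residual degrees of freedom of the fit were 3.63 and 8.

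The table held 72688 rows, of which 65956 were transcript clusters, 5222 negative controls, 1324 positive controls and 186 spike-in and background controls. Gene names came from the platform annotation: 30604 rows had 1 gene symbol, 2146 had several and 33206 transcript cluster rows had none. Symbols of 827 genes were updated through their Entrez gene ID with a RefSeq gene table of the mouse (assembly GRCm38.p6), used for names only, and 612 rows with several symbols turned out to name 1 gene. Rows naming several genes were not used, so that Ccl21a, Nrp1 and Egfl7 had no row of their own, and only 14 of 31 ribosomal protein genes and 6 of 13 mitochondrially encoded genes were tested. Each of 30743 genes was represented by its brightest row, and the 19675 genes above the array's median of all rows on at least 3 of the 12 arrays were tested. Genes from families of close copies, such as Ly6c1 and Ly6c2, Klrb1f and Serpina3n, can share probes and are uncertain as single genes. No coordinates are given because no genome build is named.

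Group means were fitted with limma (version 3.58.1, with statmod 1.5.0, in R 4.3.3), using lmFit on all 12 arrays so that the groups share an estimate of the spread, and eBayes. Contrasts were col LEC minus cap LEC, pre-col LEC minus cap LEC, col LEC minus pre-col LEC, the mean of the 3 LEC groups minus BEC, and pre-col LEC minus the midpoint of cap and col LEC. P-values were adjusted by the Benjamini-Hochberg method over the genes tested, and a gene was called at an adjusted p under 0.05. All tests are two-sided. Errors beside log2 fold changes are limma's moderated standard errors, and errors beside levels are standard deviations over 3 arrays. Genes highest in 1 subtype are an intersection of calls and have no p of their own. The position of an array between cap and col LEC is a median over the genes called between these groups. The overlap of calls was set against independent lists. The correlation of the contrasts was set against 100 simulations of unchanged groups, in which genes varied independently of each other. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15, with pandas 2.3.3.

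The groups, tests, alternatives, gene lists and the rule for naming genes were chosen before the data were examined, except the alternatives for the position of pre-col LEC and those said to be added. The rule named the sort genes first. For each comparison it then named the 10 higher and 10 lower genes with the largest fold change among those called without overlap between groups. It left out predicted genes, small RNAs, olfactory and vomeronasal receptor families and immune receptor segments. Next came the 10 genes that most exceeded the nearest group, and up to 4 called members of each list, or 2 with the smallest p. The 28 biology lists came from general knowledge: lymphatic identity, lymphatic capillary, lymphatic valve, pan-endothelial, blood capillary, venous, arterial, cell junction, basement membrane and matrix, integrins, Notch, BMP and TGF-beta, VEGF and angiopoietin, flow-responsive, planar polarity and Wnt, axon guidance, leukocyte trafficking, antigen presentation, interferon response, lipid handling, cholesterol synthesis, hypoxia and glycolysis, scavenger and endocytic receptors, contractile and cytoskeletal, immediate early and dissociation, cell cycle, ribosomal proteins and mitochondrially encoded. The 15 lists for other cells were keratinocyte, fibroblast, mural, macrophage and dendritic, T and NK, mast, neutrophil, melanocyte, Schwann, erythroid and platelet, adipocyte, chondrocyte, skeletal muscle, sebocyte and sex-linked. Some genes stand in more than 1 list, among them Lyve1, Mrc1, Acta2 and Fabp4. Lists with at least 3 genes were tested with camera at a preset correlation of 0.01 between genes, adjusted over the 43 lists within a comparison. Camera with an estimated correlation and fry, which asks whether a list moves on balance without comparing it with other genes, were alternatives.

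Further alternatives were cyclic loess between arrays, a shift to a common 75th percentile, no filter or a filter at the 75th percentile, eBayes with trend and robust settings, array weights, only the groups compared in the fit, the replicate number as a block, other rules for several rows of a gene, an added log2 fold change of at least 1, an adjusted p under 0.01, and leaving out each array in turn. The list shifts without pre-col LEC replicate 1 were given a closer look only after its markers had been seen. The procedure was tested on simulated data built on the 19675 genes, with 50 genes changed per size. For col LEC against cap LEC it called 25, 46, 49 and 50 of them at log2 changes of 0.5, 1, 2 and 3 and called 10 unchanged genes. For LEC against BEC it called 33, 49, 49 and 50 and 12 unchanged genes. A list shifted by 0.5 was called, and 0 of 40 unshifted lists were. The simulated genes varied independently of each other and the lists were random. This check therefore cannot tell how often camera calls unshifted lists whose genes vary together.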

Results

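Gene expression was measured in endothelial cells sorted from mouse ear skin to compare the cells that line successive parts of the lymphatic vessel tree with each other and with cells that line blood vessels. The mice were C57BL6, 5 weeks old, and carried a Prox1-GFP reporter. In it, a green fluorescent protein marks lymphatic endothelial cells (LEC). LEC were divided by their surface level of LYVE1, a hyaluronan receptor, into capillary cells with high LYVE1 (cap LEC), pre-collecting vessel cells with intermediate LYVE1 (pre-col LEC) and collecting vessel cells with low or no LYVE1 (col LEC). Blood endothelial cells (BEC) carried PECAM1 but none of the lymphatic markers used in the sort. Each of the 4 groups had 3 arrays labelled as biological replicates, 12 arrays in all, and 19675 genes were tested. The median RMA value of an array lay between 6.06 and 6.17 on the log2 scale. Correlations across the genes tested were 0.971 to 0.988 within a group, 0.973 to 0.989 between arrays of different LEC groups and 0.904 to 0.923 between LEC and BEC arrays. The number of arrays limits the precision of every comparison.

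The genes behind the sort followed the group labels. Lyve1 (transcript cluster TC0700004104.mm.1) had a mean log2 value of 13.08 ± 0.06 in cap LEC, 12.64 ± 0.15 in pre-col LEC, 10.44 ± 0.35 in col LEC and 6.84 ± 0.40 in BEC (SD, n = 3 in each group). Prox1 (TC0100003791.mm.1), the transcription factor that sets lymphatic identity, was at 12.53 ± 0.04, 12.51 ± 0.11 and 12.55 ± 0.05 in cap, pre-col and col LEC and at 6.93 ± 0.54 in BEC. Pdpn (TC0400003917.mm.1), which encodes podoplanin, was at 12.15 ± 0.07, 12.09 ± 0.08 and 11.89 ± 0.15 in the same LEC groups and at 7.14 ± 0.25 in BEC. Pecam1 (TC1100003932.mm.1), an adhesion molecule of all endothelium, was at 12.21 ± 0.02, 12.22 ± 0.05 and 12.26 ± 0.01 in the LEC groups and at 12.51 ± 0.11 in BEC. Because cells were selected on these proteins, their differences check the labels and are not findings.

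**Figure D1:**
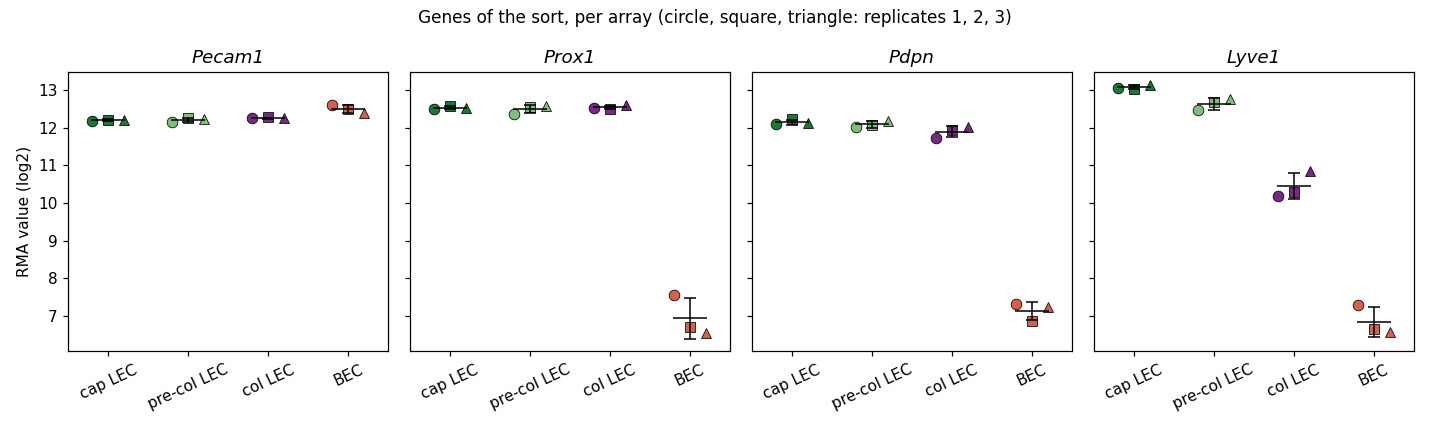
RMA values (log2, y axis) of Pecam1, Prox1, Pdpn and Lyve1 in each of the 12 arrays, by group (x axis). Symbols stand for replicates 1, 2 and 3, and the bars give the mean and SD of 3 arrays; Lyve1 falls from 13.08 in cap LEC to 10.44 in col LEC, and Prox1 and Pdpn separate LEC from BEC.

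Collecting vessel cells were first set against capillary cells, the ends of the LYVE1 gradient. Slco2a1 (TC0900001297.mm.1), the prostaglandin transporter, was higher by a log2 fold change of 2.35 ± 0.19 (SE, n = 3 arrays per group, adjusted p = 7.96e-05). Parm1, a mucin-like membrane protein, was higher by 2.07 ± 0.10 (adjusted p = 2.29e-06), and Adm, the vasoactive peptide adrenomedullin, by 1.79 ± 0.16 (adjusted p = 0.000127). The matrix protease Adamts1 (2.10), the TGF-beta family ligand Gdf10 (2.07), the endothelial receptor Cd93 (1.71) and the protocadherin Pcdh7 (1.68) were also higher. So were Klrb1f (2.32), Sbspon (2.22) and Ccdc3 (1.69). After Lyve1 itself (-2.64 ± 0.20), the genes most reduced in col LEC were Antxr2, a receptor for matrix proteins, at -2.50 ± 0.22 (adjusted p = 0.000127), and the adaptor gene Shc3 at -2.08 ± 0.39 (adjusted p = 0.0198). Aqp1 (TC0600000664.mm.1), a water channel, was at -2.07 ± 0.10 (adjusted p = 2.29e-06). The ectonucleotidase Enpp3 (-2.01), the mannose receptor Mrc1 (-1.88), the protease inhibitor Serpina3n (-1.79), the hyaluronan-associated Itih5 (-1.78), the protocadherin Pcdh17 (-1.77) and the receptor Gpr31b (-1.67) were lower as well. In all, 322 genes passed limma's test at adjusted p under 0.05, 128 higher and 194 lower in col LEC. Of these, 96 differed at least 2-fold (40 higher and 56 lower). Leaving out 1 array lowered the count to 197, 195 and 203 without col LEC replicates 1, 2 and 3 and to 205, 183 and 180 without cap LEC replicates 1, 2 and 3. Array weights raised it to 792. Shc3 lost its call in 5 of these 6 fits (highest adjusted p = 0.095, without cap LEC replicate 3, with a log2 fold change of -1.97). Gpr31b lost its call in 3 (highest adjusted p = 0.0829, without cap LEC replicate 2, at -1.61).

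**Figure D2:**
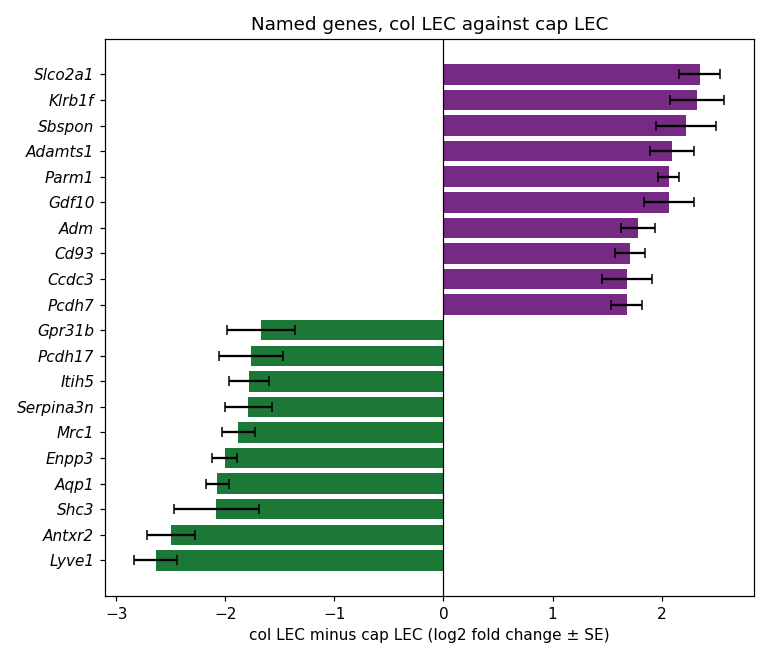
Log2 fold change of col LEC over cap LEC (x axis) for the 10 genes most raised and the 10 most reduced among those that passed the test and did not overlap between groups (y axis). Bars start at 0 and error bars give the SE from 3 arrays per group; values run from -2.64 for Lyve1 to 2.35 for Slco2a1.

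Of 9 measured lymphatic capillary genes, 3 were lower over all genes tested and 4 when adjusted over the list alone. Lyve1, Mrc1 and the stretch-activated channel gene Piezo2 (-1.51 ± 0.18) led them, with a list median of -0.33 (camera adjusted p = 6.14e-08, and adjusted p = 0.247 with an estimated correlation). Of 12 lymphatic identity genes, Lyve1 and Flt4, the receptor for VEGF-C (-0.49 ± 0.11, adjusted p = 0.0482), were lower. When adjusted over the list alone, 5 were lower (median -0.33, camera adjusted p = 2.66e-06, and adjusted p = 0.361 with an estimated correlation). Lyve1, chosen by the sort, is a member of both. Flt4 lost its call without each of the 6 arrays in turn (highest adjusted p = 0.19, without col LEC replicate 1, at -0.42) and under cyclic loess (adjusted p = 0.116). The scavenger and endocytic receptor list, with Lyve1 and Mrc1 lower among 16 genes, was not called by camera (adjusted p = 0.0703), but by fry (adjusted p = 0.02) and by camera without cap LEC replicate 3 (adjusted p = 0.0268). Outside these lists, the Wnt amplifier Rspo3 (-1.51), the chemokine-scavenging receptor Ackr2 (-1.23) and the immune-inhibitory ligand Cd200 (-0.84) were lower in col LEC.

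The lists tied to valves and to flow had medians above 0 in col LEC minus cap LEC. The flow-responsive list had 3 of 14 genes higher and 7 when adjusted over the list alone, with a median of 0.20 (camera adjusted p = 0.000722, and adjusted p = 0.361 with an estimated correlation). Its members included Nos3, the endothelial nitric oxide synthase (1.38 ± 0.12), the vasoconstrictor peptide gene Edn1 (0.70 ± 0.14) and the growth factor gene Pdgfb (0.55 ± 0.11). Of 19 lymphatic valve genes only the netrin receptor gene Neo1 (1.15 ± 0.14) was higher over all genes tested, with 6 higher when adjusted over the list alone (median 0.26, camera adjusted p = 0.00165, and adjusted p = 0.546 with an estimated correlation). The immediate early and dissociation list, genes that respond within minutes to handling of cells, had a median of 0.25 with 20 of 23 genes above 0 (camera adjusted p = 0.000365, and adjusted p = 0.546 with an estimated correlation). No member was called over all genes, and 1 was called higher when adjusted over the list alone. Single genes of other lists that were higher were the tight junction gene Cldn11 (1.59), the ephrin receptor gene Epha4 (1.56), Bmp4 (1.27), Mmrn2 (1.10), the laminin-binding integrin gene Itga3 (0.92) and the lipoprotein gene Apoe (0.88). Edn1 lost its call without each of the 6 arrays (highest adjusted p = 0.117, without cap LEC replicate 2, at 0.65) and Pdgfb in 4 of the 6 fits (highest adjusted p = 0.0975, without col LEC replicate 2, at 0.50). The valve list lost its call without cap LEC replicate 1 (adjusted p = 0.056).

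Of the lists with smaller shifts, basement membrane and matrix had a median of -0.14 over 28 genes (camera adjusted p = 0.0146), cell cycle -0.20 over 20 genes (adjusted p = 0.00151) and cholesterol synthesis -0.13 over 16 genes (adjusted p = 0.0178). With an estimated correlation these became adjusted p = 0.576, 0.546 and 0.546. The matrix gene Tnxb (-1.07 ± 0.10), which encodes tenascin X, was the only member of the 3 lists called over all genes. When adjusted over the list alone, 3 matrix genes were higher and 6 lower, against 1 lower in each of the cell cycle and cholesterol lists. The basement membrane call ended without col LEC replicate 1 (adjusted p = 0.105) and under cyclic loess (adjusted p = 0.0663). The cholesterol call ended without col LEC replicate 1 (adjusted p = 0.155), without cap LEC replicate 3 (adjusted p = 0.0501) and with array weights (adjusted p = 0.0917). The cell cycle call ended without cap LEC replicate 3 (adjusted p = 0.0501). Camera also called the pan-endothelial and junction lists higher after cyclic loess (adjusted p = 0.0246 and 0.0424) and the keratinocyte list higher without col LEC replicate 2 or BEC replicate 3 (adjusted p = 0.0115 and 0.024). Without cap LEC replicate 3 it called the pan-endothelial list higher and the blood capillary list lower (adjusted p = 0.045 and 0.0312). By camera, 8 of 43 lists were called in this comparison, by fry 9, and with an estimated correlation 0. The camera and fry calls were only partly the same lists. Fry did not call the valve (adjusted p = 0.118), immediate early (0.151), basement membrane (0.247), cell cycle (0.247) and cholesterol (0.237) lists. It called the blood capillary, venous and cell junction lists (adjusted p = 0.0229, 0.0026 and 0.00323), which camera did not call in the main setting.

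Pre-collecting cells were next set against capillary cells. No gene passed limma's test (0 of 19675, smallest adjusted p = 0.0691), while 1257 genes (6.39%) had an unadjusted p under 0.05. The same contrast gave 28 genes with array weights, 13 after cyclic loess between arrays, and 1 gene without pre-col LEC replicate 1 or without cap LEC replicate 1. Among list members, Neo1 was at 0.87 ± 0.14 (adjusted p = 0.0846), Cldn11 at 0.87 ± 0.14 (adjusted p = 0.0846), Mrc1 at -0.68 ± 0.15 (adjusted p = 0.363), Piezo2 at -0.57 ± 0.18 (adjusted p = 0.65) and Lyve1 at -0.45 ± 0.20 (adjusted p = 0.775). Markers of mural cells, the contractile cells around vessels, and of fibroblasts moved with this contrast. The mural list had a median of 0.27 over 13 genes and the fibroblast list 0.36 over 12 genes (camera adjusted p = 0.000387 for both, and adjusted p = 0.752 with an estimated correlation), with 0 members called. Most of that lay on 1 array, pre-col LEC replicate 1, where Rgs5, a pericyte gene, was at 10.2 and the smooth muscle actin gene Acta2 at 10.2, against 8.91 and 8.0 in replicate 2 and 7.93 and 6.84 in replicate 3. Without that array the mural median was 0.085 (adjusted p = 0.0733) and the fibroblast median 0.11 (adjusted p = 0.117).

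The other 7 lists called between pre-col and cap LEC were lymphatic identity (median -0.15, adjusted p = 0.0472), flow-responsive (median 0.06, adjusted p = 0.041), cholesterol synthesis (median -0.08, adjusted p = 0.0472), cell cycle (median -0.20, adjusted p = 0.0182), ribosomal proteins (median -0.08, adjusted p = 0.041), mitochondrially encoded genes (median 0.19, adjusted p = 0.0472) and skeletal muscle (median 0.17, adjusted p = 0.041). With an estimated correlation all 9 lists called here had adjusted p = 0.752, and fry called 0. No member of any of the 9 lists was called over all genes, and 2 flow-responsive genes were higher when adjusted over the list alone. Without pre-col LEC replicate 1 the adjusted p was 0.417 for lymphatic identity, 0.0992 for cholesterol synthesis, 0.0733 for cell cycle and ribosomal proteins, 0.617 for mitochondrially encoded genes and 0.489 for skeletal muscle. Flow-responsive and ribosomal calls ended without pre-col LEC replicate 2 (adjusted p = 0.275 and 0.163). Identity, cholesterol and mitochondrial calls ended without pre-col LEC replicate 3 (adjusted p = 0.075, 0.126 and 0.0613). Without cap LEC replicate 1 the flow-responsive, cholesterol, ribosomal and mitochondrial lists had adjusted p = 0.17, 0.0581, 0.0529 and 0.127. Without cap LEC replicate 2 the identity, mitochondrial and muscle lists had adjusted p = 0.167, 0.102 and 0.091. Without cap LEC replicate 3 the identity, cholesterol, cell cycle, ribosomal and muscle lists had adjusted p = 0.14, 0.166, 0.254, 0.113 and 0.166. Without BEC replicate 1 the mitochondrial list had adjusted p = 0.0604. Array weights ended all 7 of these calls (adjusted p = 0.0623 to 0.135). Cyclic loess ended the identity, ribosomal and muscle calls (adjusted p = 0.191, 0.223 and 0.0516), and testing without the filter on dim genes ended the flow-responsive and mitochondrial calls (adjusted p = 0.0598 for both). Calls were gained as well. The lymphatic valve list was called higher in pre-col LEC without pre-col LEC replicate 1 (adjusted p = 0.00759), without cap LEC replicate 3 (adjusted p = 0.0455) and after cyclic loess (adjusted p = 0.00432), which also gained the pan-endothelial and junction lists as higher (adjusted p = 0.0316 and 0.019). Without pre-col LEC replicate 2 the lymphatic capillary list was called lower and antigen presentation higher (adjusted p = 0.02 and 0.042). Without cap LEC replicate 1 the antigen presentation, macrophage, neutrophil and adipocyte lists were called higher (adjusted p = 0.0316 for the first and 0.0349 for the others), and without BEC replicate 3 the keratinocyte list (adjusted p = 0.0427).

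**Figure D3:**
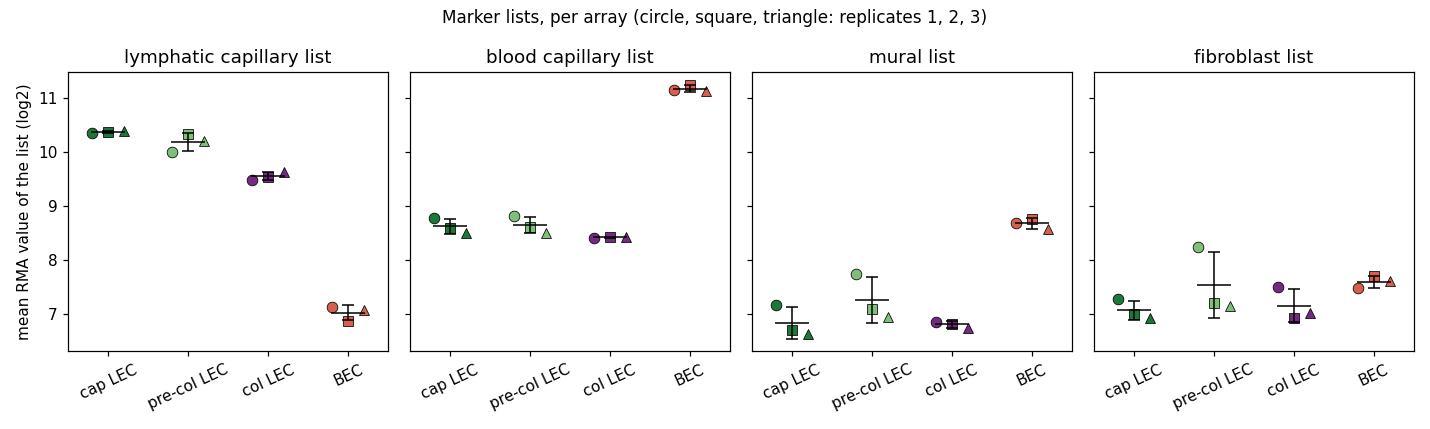
Mean RMA value (log2, y axis) of the genes of the lymphatic capillary, blood capillary, mural and fibroblast lists in each of the 12 arrays, by group (x axis). Symbols stand for replicates 1, 2 and 3 and bars give the mean and SD of 3 arrays; pre-col LEC replicate 1 has the highest mural (7.74) and fibroblast (8.24) means of the 9 LEC arrays, and the mural mean of BEC is 8.68 ± 0.10.

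Collecting cells were then set against pre-collecting cells. Slco2a1 was higher in col LEC by 1.62 ± 0.19 (adjusted p = 0.00387), Parm1 by 1.45 ± 0.10 (adjusted p = 6.65e-05), Pcdh7 by 1.39 ± 0.14 and Adm by 1.18 ± 0.16 (n = 3 arrays per group). The plasma glycoprotein gene Ahsg (1.33), Adamts1 (1.28), the kinase gene Nuak1 (1.21), the hyaluronan-binding Itih2 (1.19), the cytokine receptor gene Il13ra1 (0.91), the lipoprotein receptor gene Lsr (0.91) and Nos3 (0.85) were also higher. Lyve1 was lower by a log2 fold change of -2.19 ± 0.20, Aqp1 by -1.88 ± 0.10 (adjusted p = 1.39e-05), Antxr2 by -1.62 ± 0.22, Enpp3 by -1.47 ± 0.11 and Rspo3 by -1.31 ± 0.17. Itih5 (-1.26), Mrc1 (-1.20), the membrane repair gene Dysf (-1.10), the actin-binding Ablim3 (-1.04) and the motor protein gene Myo5b (-1.03) completed the lower genes. The test called 59 genes, 23 higher and 36 lower. Of these, 23 differed at least 2-fold. The count was 24 and 32 without col LEC replicates 1 and 2, 27 and 35 without pre-col LEC replicates 2 and 3. It was 5 when only the groups compared were fitted and 153 with array weights (78 higher and 75 lower). Of the 25 named genes called here, 14 kept their call in all 6 fits that left out 1 array. Among the other 11, Mmrn2, Ptx3 and Slc2a1 lost theirs in all 6 fits and Tnxb in 5, with a highest adjusted p of 0.203, 0.195, 0.145 and 0.136 without col LEC replicate 2, col LEC replicate 3, pre-col LEC replicate 2 and col LEC replicate 1. Il13ra1 lost its call in 5, Adamts1 and Itih5 in 4, Dysf, Nos3 and Myo5b in 2 and Antxr2 in 1. The highest adjusted p was 0.0808 for Adamts1 and 0.0782 for Itih5 without col LEC replicate 2. It was 0.0948 for Il13ra1 and 0.106 for Dysf without pre-col LEC replicate 2, and 0.056 for Antxr2, 0.0618 for Nos3 and 0.0682 for Myo5b without col LEC replicate 1.

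Of the lists, lymphatic capillary genes had 3 of 9 lower (4 when adjusted over the list alone) with a median of -0.50 (camera adjusted p = 3.14e-11, and adjusted p = 0.0949 with an estimated correlation). The identity list (1 of 12 lower, median -0.20, adjusted p = 1.05e-05) and the scavenger receptor list (2 of 16 lower, median -0.05, adjusted p = 0.00119) had Lyve1 among the genes called, with Mrc1 in the second list only, and had adjusted p = 0.319 and adjusted p = 0.266 with an estimated correlation. Immediate early genes had a median of 0.25 with none called over all genes and 3 higher when adjusted over the list alone (adjusted p = 2.16e-06, and adjusted p = 0.319 with an estimated correlation). The flow-responsive list had a median of 0.09 with Nos3 called (adjusted p = 0.00639) and the valve list a median of 0.10 with none called (adjusted p = 0.0121). With an estimated correlation these were adjusted p = 0.319 and adjusted p = 0.667. Mural (median -0.29, adjusted p = 1.05e-05) and fibroblast genes (median -0.22, adjusted p = 0.00015) were lower as lists with 0 members called, and had adjusted p = 0.332 and adjusted p = 0.497 with an estimated correlation. Basement membrane and matrix (-0.08, adjusted p = 0.00119), contractile and cytoskeletal (-0.10, adjusted p = 0.00585) and macrophage and dendritic genes (-0.03, adjusted p = 0.0302) completed the 11 lists called. They had adjusted p = 0.497, adjusted p = 0.266 and adjusted p = 0.566 with an estimated correlation. Fry called 4 lists in this comparison, against the 11 by camera. Without pre-col LEC replicate 1, whose mural and fibroblast markers were high, the adjusted p was 0.0502 for mural, 0.532 for fibroblast and for valve, 0.123 for flow-responsive, 0.0585 for contractile and 0.138 for macrophage genes. Without col LEC replicate 1 the basement membrane list had adjusted p = 0.105 and the contractile list 0.131. Without col LEC replicate 2 the valve list had adjusted p = 0.226 and the macrophage list 0.134. Without pre-col LEC replicate 2 the basement membrane list had adjusted p = 0.0896 and the contractile list 0.0538. The macrophage call also ended without col LEC replicate 3 (adjusted p = 0.0651) and pre-col LEC replicate 3 (adjusted p = 0.168). The contractile call also ended with array weights (adjusted p = 0.0691). Camera gained the arterial list as lower without the filter on dim genes (adjusted p = 0.0273), without col LEC replicate 2 (adjusted p = 0.0436) and without pre-col LEC replicate 3 (adjusted p = 0.00452). Without pre-col LEC replicate 3 the blood capillary, interferon and skeletal muscle lists were also called lower (adjusted p = 0.00909, 0.0459 and 0.0459). Without pre-col LEC replicate 2 the pan-endothelial list was called higher and the mitochondrial list lower (adjusted p = 0.0293 and 0.00856). When adjusted over the list alone, 1 identity, 2 scavenger receptor and 1 matrix gene were lower, 4 flow-responsive genes and 1 valve gene were higher, and no mural, fibroblast, contractile or macrophage gene was called.

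Where pre-collecting cells lie between the other LEC groups was tested gene by gene against the midpoint of cap and col LEC. Only Aqp1 passed this test over all genes. Its pre-col LEC level of 11.17 was above the midpoint of the capillary level of 11.37 and the collecting level of 9.30 by 0.84 ± 0.09 (limma adjusted p = 0.0183). It was the 1 gene called, against 755 genes (3.84%) at an unadjusted p under 0.05. Genes not called may depart from the midpoint too. The sort gene Lyve1, not called, had means of 13.08, 12.64 and 10.44 in cap, pre-col and col LEC. The Aqp1 call was lost in 5 of 9 fits that left out 1 array (highest adjusted p = 0.21, without pre-col LEC replicate 1, at 0.80). No gene was called without col LEC replicate 1, any pre-col LEC replicate or cap LEC replicate 2. There were 2 genes called without cap LEC replicate 1 and 2 without cap LEC replicate 3. Over the 322 genes called between col and cap LEC, 310 (96.3%) had a pre-col LEC mean between the other means. Of the 322, 220 were nearer to cap LEC and 102 nearer to col LEC. These genes were chosen on the same arrays for a large gap between the cap and col LEC means. That choice favours a pre-col LEC mean between them, so the share alone does not show that pre-col LEC are intermediate. On a scale where the cap LEC mean is 0 and the col LEC mean is 1, the median gene of pre-col LEC stood at 0.397 ± 0.040 (SD, n = 3; arrays at 0.443, 0.370 and 0.379). BEC, scored on the same genes, stood at 0.775 ± 0.065, and the BEC mean of 96 of them (29.8%) lay between the cap and col LEC means.

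**Figure D4:**
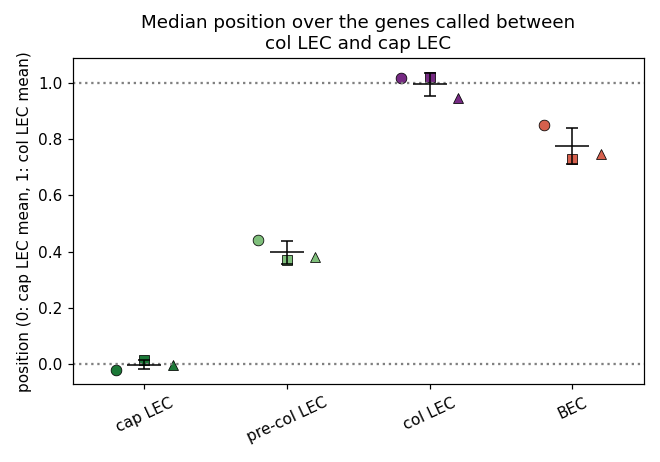
Median position (y axis, 0 for the cap LEC mean and 1 for the col LEC mean, no unit) over the 322 genes called between col and cap LEC, for each of the 12 arrays by group (x axis). Symbols stand for replicates 1, 2 and 3 and bars give the mean and SD of 3 arrays; the pre-col LEC arrays lie between 0.370 and 0.443. The cap and col LEC arrays sit at the ends by construction, and the choice of genes with a gap between them favours a place between for pre-col LEC.

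A gene was counted as highest in 1 LEC subtype when it was higher there than in each other LEC subtype and in BEC. There were 15 such genes for col LEC and, by the same limma calls, 0 for pre-col LEC and 0 for cap LEC. Of the col LEC genes, Parm1 exceeded the nearest group by a log2 fold change of 1.41, Pcdh7 by 1.39, Ahsg by 1.33, Itih2 by 1.19 and Adm by 1.18. Lsr (0.91), the growth factor gene Tgfa (0.83), the transcription factor genes Gata6 (0.82) and Foxp2 (0.61), and Prr15 (0.75) followed. The count was 9 without col LEC replicate 2, pre-col LEC replicate 1 or pre-col LEC replicate 2, and 54 with array weights. That no gene was called highest in pre-col or cap LEC follows from the contrast between them, where 0 genes were called (1257 at an unadjusted p under 0.05).

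Lymphatic and blood endothelial cells differed far more widely than the LEC groups did among themselves. Besides the sort genes, LEC exceeded BEC in Tc2n by a log2 fold change of 6.10 ± 0.16 (SE, 9 LEC and 3 BEC arrays, adjusted p = 1.43e-10). They exceeded BEC in the guidance ligand gene Sema3d by 5.56 ± 0.29, in the matrix gene Mmrn1 by 5.36 ± 0.53 and in Reln, which encodes the secreted glycoprotein reelin, by 5.35 ± 0.23. Pkhd1l1 (5.04), the polarity gene Pard6g (5.00), the transcription factor gene Maf (4.75) and the lymphocyte survival cytokine gene Il7 (3.89) were also higher in LEC. BEC exceeded LEC in the junction gene Jam2 (LEC minus BEC -5.95 ± 0.30, adjusted p = 2.13e-08), the matrix gene Sparcl1 (-5.48 ± 0.60), and the leukocyte-rolling receptor gene Sele (-5.41 ± 0.26). They also exceeded LEC in the chemokine receptor gene Cxcr4 (-5.06 ± 0.15), the apelin receptor gene Aplnr (-5.04 ± 0.18) and the VEGF receptor gene Flt1 (-5.01 ± 0.21). Ly6c2 (-5.37), AW112010 (-5.13), Ly6c1 (-5.11) and Kitl (-4.92) were lower in LEC too. Ly6c1 and Ly6c2 are near-identical copies whose probes cannot be taken as separate. By limma 4453 of 19675 genes were called, 2370 higher and 2083 lower in LEC. The counts higher and lower were 2043 and 2225 after cyclic loess, 2215 and 2281 without the filter on dim genes and 1904 and 1910 with array weights. Of the 4453 genes, 998 differed at least 2-fold (421 higher and 577 lower). Against BEC alone, col LEC differed in 3196 genes, pre-col LEC in 3055 and cap LEC in 4073.

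Of the vessel-type lists, all 9 lymphatic capillary genes were higher in LEC (median 2.82, camera adjusted p = 2.08e-13), as were 10 of 12 identity genes (11 when adjusted over the list alone, median 2.21, adjusted p = 2.54e-14). The sort genes Lyve1 and Pdpn stand in both lists and Prox1 in the identity list, so the sort set part of both shifts. Blood capillary genes were lower for 10 of 12 (median -2.52, adjusted p = 1.42e-13). They were led by Flt1, the glycerol channel gene Aqp7 (-4.88), the fatty acid receptor gene Cd36 (-4.47) and Cd34 (-4.22). Venous genes were lower for 6 of 10 (7 when adjusted over the list alone, median -1.47, adjusted p = 0.00038), among them Selp (-4.24), Vwf (-3.80) and the chemokine-binding receptor gene Ackr1 (-2.48), and 1 was higher. Pan-endothelial genes were lower for 10 of 13 (11 when adjusted over the list alone, median -0.69, adjusted p = 8.86e-07), including the junction gene Esam (-2.48), Clec14a (-2.18) and the phosphatase gene Ptprb (-1.57). With an estimated correlation these 5 lists held, at adjusted p = 0.0214, 0.0239, 0.00548, 0.0239 and 0.0456 in the order given. Arterial genes (9 of 15 lower and 5 higher, median -0.82, adjusted p = 0.0155), with Cxcl12 (-3.67) and the transcription factor gene Sox17 (-2.88) lower, had adjusted p = 0.302 with an estimated correlation. Valve genes were higher for 10 of 19 and lower for 4 (median 0.33, adjusted p = 0.00429, and adjusted p = 0.468 with an estimated correlation). Among them, the semaphorin gene Sema3a (3.18), the polarity gene Celsr1 (2.05) and the integrin gene Itga9 (1.5) were higher and the laminin gene Lama5 (-1.69) was lower. When adjusted over the list alone, 10 blood capillary genes were lower, 9 arterial genes were lower and 6 higher, and 11 valve genes were higher and 4 lower.

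Of the other biology lists, interferon response genes were lower in LEC for 19 of 21 (19 when adjusted over the list alone, median -1.29, camera adjusted p = 4.04e-14), with the antiviral genes Rsad2 (-3.29 ± 0.21), Rtp4 (-2.93 ± 0.28), Irf7 (-1.82 ± 0.09) and the RNA sensor gene Ifih1 (-1.69 ± 0.12). Lipid handling genes were lower for 12 of 21 and higher for 3 (median -0.59, adjusted p = 1.62e-05), with the lipoprotein receptor gene Scarb1 (-3.96), the fatty acid binding protein gene Fabp4 (-3.91) and the lipid transfer gene Pltp (-3.57). Leukocyte trafficking genes were lower for 16 of 30 and higher for 8 (median -0.69, adjusted p = 0.000407). With an estimated correlation the interferon, lipid and trafficking lists held, at adjusted p = 0.00548, 0.0239 and 0.0239. Antigen presentation genes were lower for 10 of 18 (median -0.71, adjusted p = 0.000132, and adjusted p = 0.275 with an estimated correlation), among them the immunoproteasome genes Psmb10 (-1.40) and Psmb8 (-1.29) and the peptide transporter gene Tap1 (-1.19). Notch genes (9 of 17 lower and 3 higher, adjusted p = 0.0115), cell junction genes (9 of 25 lower and 5 higher, adjusted p = 0.0262) and immediate early genes (7 of 23 lower and 2 higher, adjusted p = 0.0117) had adjusted p = 0.201, adjusted p = 0.0885 and adjusted p = 0.583 with an estimated correlation. Notch2 (2.31) was higher, and Notch3 (-1.70) and Notch4 (-1.46) were lower. The immediate early call ended without BEC replicate 1 (adjusted p = 0.0972) and with array weights (adjusted p = 0.0837). When adjusted over the list alone, the counts lower were 12 for lipid handling, 17 for trafficking, 10 for antigen presentation, 10 for Notch, 10 for junctions and 11 for immediate early genes.

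There were 6 biology lists that camera called in none of the 4 comparisons, although many members differed between LEC and BEC. Axon guidance genes were higher in LEC for 14 of 32 and lower for 15 (adjusted p = 0.981), with Sema3d and Sema3a higher and Sema7a (-3.98) lower. The BMP and TGF-beta list had 9 of 24 higher and 10 lower (adjusted p = 0.979), with the matrix gene Tgfbi (3.74), Tgfb3 (2.72) and the receptor gene Tgfbr2 (1.52) higher. Its median was -0.11 and its mean 0.24. Integrins had 5 of 14 higher and 6 lower (adjusted p = 0.792), with Itgb3 (2.27) higher and Itgb5 (-1.71) lower. Their median was -0.30 and their mean 0.03. The VEGF and angiopoietin list had 6 of 21 higher and 6 lower (adjusted p = 0.632), with Flt4 (2.70) higher and the apelin gene Apln (-4.75) lower. Planar polarity and Wnt genes were higher for 5 of 22 and lower for 5 (adjusted p = 0.565), with Rspo3 (2.80) higher and the receptor gene Fzd4 (-1.11) lower. Hypoxia and glycolysis genes were higher for 3 of 23 and lower for 8 (adjusted p = 0.184), with the glycolysis activator gene Pfkfb3 (-0.99) lower. When adjusted over the list alone, the counts higher and lower were 16 and 16 for axon guidance, 9 and 11 for BMP and TGF-beta, 5 and 8 for integrins, 8 and 6 for VEGF, 5 and 6 for planar polarity and 4 and 8 for hypoxia. Fry, which asks whether a list moves on balance, called 4 of these lists between LEC and BEC: VEGF (adjusted p = 4.43e-05), BMP and TGF-beta (adjusted p = 0.00316), planar polarity (adjusted p = 0.0115) and hypoxia (adjusted p = 0.0212). It also called hypoxia and integrins between col and cap LEC (adjusted p = 0.02 and 0.041) and hypoxia between col and pre-col LEC (adjusted p = 0.0236). Camera called hypoxia in that last comparison without the filter on dim genes (adjusted p = 0.0382).

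Marker lists of other skin cells also differed between LEC and BEC. Mural genes were lower in LEC for 12 of 13 (13 when adjusted over the list alone, median -1.53, camera adjusted p = 1.27e-10, and adjusted p = 0.0885 with an estimated correlation). In BEC, the pericyte genes Rgs5, Pdgfrb and Abcc9 were at 11.45 ± 0.35, 10.78 ± 0.25 and 9.84 ± 0.47 and Acta2 at 10.32 ± 0.40 (SD, n = 3). LEC minus BEC was -3.50 ± 0.49, -3.37 ± 0.29, -3.16 ± 0.21 and -2.84 ± 0.50 (SE) in the same order. Acta2 overlapped between LEC and BEC arrays because pre-col LEC replicate 1 was at 10.2. These mural differences stand beside every blood vessel list above. Keratinocyte (3 of 12 lower, median -0.25, adjusted p = 0.0262), mast cell (1 of 3 lower, Kit at -2.21, median -0.44, adjusted p = 0.0401) and erythroid and platelet genes (1 of 5 lower, median -0.38, adjusted p = 0.0417) were called. They had adjusted p = 0.61, adjusted p = 0.185 and adjusted p = 0.4 with an estimated correlation. Adjusted over the list alone, 4 keratinocyte, 2 mast cell, 4 erythroid and platelet and 6 fibroblast genes were lower. The keratinocyte call ended without BEC replicate 3 (adjusted p = 0.108) and after cyclic loess (adjusted p = 0.0687). The mast cell call ended without BEC replicate 2 (adjusted p = 0.0722), after cyclic loess (adjusted p = 0.0687) and without the filter on dim genes (adjusted p = 0.0757). The erythroid and platelet call ended without pre-col LEC replicate 2 (adjusted p = 0.0517), BEC replicate 2 (adjusted p = 0.103) and BEC replicate 3 (adjusted p = 0.0571). Fibroblast genes, lower for 3 of 12, were not called by camera (adjusted p = 0.0976). They were called lower in LEC without pre-col LEC replicate 1, the array with high fibroblast markers (adjusted p = 0.00608), and with array weights (adjusted p = 0.0461). Without that array the contractile and skeletal muscle lists were called lower too (adjusted p = 0.0463 and 0.0411), the contractile list also after cyclic loess (adjusted p = 0.035), and ribosomal proteins were called higher without the filter on dim genes (adjusted p = 0.03). T and NK cell (adjusted p = 0.565), neutrophil (adjusted p = 0.186), melanocyte (adjusted p = 0.561), Schwann cell (adjusted p = 0.895), adipocyte (adjusted p = 0.561), chondrocyte (adjusted p = 0.834), sebocyte (adjusted p = 0.915) and sex-linked genes (adjusted p = 0.895) were called by camera neither here nor in the other comparisons, apart from the neutrophil and adipocyte calls given above without cap LEC replicate 1. Fry called the neutrophil and adipocyte lists between LEC and BEC (adjusted p = 0.0478 and 0.0377). Median and mean differed in sign for the T and NK cell, Schwann cell and chondrocyte lists.

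The last comparison asked whether the difference between collecting and capillary cells runs along the difference between blood and lymphatic cells. Of the 194 genes lower in col LEC, Mrc1 and Rspo3 among them, 119 (61.3%) were higher in LEC than in BEC, against 23.4 for independent lists (Fisher's exact odds ratio 12.1, interval 8.99 to 16.5). The sort gene Lyve1 is counted in both. Another 40 (20.6%) were higher in BEC, against 20.5 (odds ratio 2.22). Of the 128 genes higher in col LEC, 32 (25%) were higher in BEC, Nos3 and Mmrn2 among them, against 13.6 (odds ratio 2.84). A further 55 (43.0%) were higher in LEC, against 15.4 (odds ratio 5.61). Aqp1, lower in col than in cap LEC, was higher in BEC than in LEC. The 55 and the 40 genes lay against col LEC being nearer to BEC, and they too exceeded independent lists. The other pairings together held 151 genes, in the direction of col LEC being nearer to BEC. This number was 94, 91 and 99 without col LEC replicates 1, 2 and 3, 89 and 88 without cap LEC replicates 2 and 3, and 321 with array weights. Across genes, which are not independent replicates, the contrasts col minus cap and BEC minus LEC correlated with r = 0.148 and rho = 0.221. In 100 simulations of unchanged groups r was -0.0599 to 0.0646. The simulated genes varied independently of each other, so this range leaves out variation that real genes share and may be too narrow. Fisher's interval above also counts genes as independent. The covariance of the contrasts was 0.0181, against a simulated mean of 2.59e-05.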

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

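The test of other cell markers in BEC, the tests of BEC carried into the pre-col and col LEC sorts, Fisher's exact test of the probe sets and the list medians without pre-col LEC replicate 1 were chosen only after the result was seen. Transcript cluster probe sets with no gene name or with several, which the comparisons of named genes leave out, were tested in the same way. Between col and cap LEC, 50 of 15149 such probe sets (0.330%) were called, 15 higher and 35 lower in col LEC, against 3 of 2960 negative control probe sets (0.101%, two-sided p = 0.0384 by Fisher's exact test, in which probe sets count as independent). Between col and pre-col LEC, 6 of the unnamed probe sets (0.0396%) were called, against 1 negative control probe set (0.0338%), shares that the same test did not separate (exact p = 1). Between LEC and BEC, 1363 of the unnamed probe sets (9.0%) were called, 751 higher and 612 lower in LEC, against 117 negative control probe sets (3.95%, exact p = 5.11e-23). Between pre-col and cap LEC, limma called 0 of the unnamed probe sets (4.91% at an unadjusted p under 0.05) and 1 negative control probe set. Unnamed and control probe sets were fitted and adjusted apart, so the shares called rest on unlike cutoffs. Fisher's test therefore cannot decide whether they differ. At an unadjusted p under 0.05 the shares were 7.78% and 6.76% between col and cap LEC. They were 5.00% and 6.62% between col and pre-col LEC and 21.1% and 16.25% between LEC and BEC. Called controls differed by up to 4.46 in log2 between col and cap LEC and 5.10 between LEC and BEC.

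Mural markers were higher in BEC than in LEC (list median of LEC minus BEC -1.53). In BEC, Rgs5 was at 11.45, Pdgfrb at 10.78, Acta2 at 10.32 and Abcc9 at 9.84. Cells carrying PECAM1 had been enriched on beads before the sort on podoplanin, Prox1-GFP and LYVE1. A carry-over of all skin cells alike is argued against: over the 94 markers of the 13 other lists of other cells, sex-linked genes left out, the median rise in BEC was 0.102, with a bootstrap bound of 0.137. The lists of mast cells, erythroid cells and platelets, fibroblasts and keratinocytes lay furthest towards BEC among these (medians of LEC minus BEC -0.44, -0.38, -0.27 and -0.25), and some of these cells carried along stay open. A candidate explanation is material from pericytes and smooth muscle on blood vessels that stayed with BEC through the bead enrichment and the sort. Expression of some of these genes by BEC themselves stays open too, and no test here separates the one from the other; Acta2 and Notch3 also stand in other lists.

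On pre-col LEC replicate 1, all 13 mural and 11 of 12 fibroblast markers were above the mean of the other pre-col arrays, by 0.72 and 1.06 on average; no biological explanation was tested, since the design gives none for 1 array. A shift of the whole array is argued against, since the median rise of these markers was 0.58 while 2.5% of 10000 matched random lists exceeded 0.0902. BEC carried into that sort are argued against as the source of the fibroblast markers, whose mean of 8.24 lay above the highest BEC array (7.70, SD of the BEC arrays 0.11), and as the whole source of the mural markers: these would need 26.3% of BEC at the median on the linear scale (bootstrap bound 13.02%), while the 100 other genes with the largest BEC over LEC difference showed 2.43% (bound 3.04%). An earlier comparison of mean rises, 0.25 for blood capillary against 0.72 for mural markers, did not separate them (permutation p = 0.118). Cells of the vessel wall and connective tissue carried into this sample may be behind the mural and fibroblast list calls, whose medians against cap LEC went from 0.27 and 0.36 to 0.085 and 0.11 without it.

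Of the genes lower in col LEC than in cap LEC, 61.3% were higher in LEC than in BEC. Brighter or steadier genes being called in both comparisons is argued against, since 10000 gene sets matched on level and spread reached at most 30.9% (median 19.1%), and so is a single deviating array, since the share was at least 59.5% without any 1 of the 6 arrays. BEC carried into the col LEC sort is argued against as the whole cause: the fall of the 100 genes with the largest LEC over BEC difference, sort genes left out, would need 16.5% of BEC in col LEC at the median (bootstrap bound 9.71%), while the 100 genes with the largest BEC over LEC difference, mural and fibroblast markers left out, showed 0.333% (bound 0.731%). These values are consistent with a hypothesis that collecting vessel cells have a lower level of part of the lymphatic program, found and tested on the same data. Against it stands that 43.0% of the genes higher in col LEC were also higher in LEC than in BEC; selection on LYVE1 may have favoured genes that vary with it, which was not tested.

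Other splits of the arrays were tried for each count. For the comparisons of 3 arrays with 3 there are only 10 splits, too few for a share under 0.05: col against cap LEC gave 322 genes and the highest other split 0, col against pre-col LEC gave 59 and 0, and pre-col against cap LEC gave 0 and 3. For LEC against BEC, a fit of 9 against 3 arrays gave 4382 genes and the highest of the other splits among 100 gave 5. This argues against a random grouping of the arrays. The other splits mix LEC and BEC arrays on at least 1 side. The gap between these cells then adds to the spread and keeps their counts low. For the 15 genes highest in 1 LEC subtype, the highest of the other splits among 100 gave 10. The splits with 8 to 10 genes kept the 3 col LEC arrays together, so they still hold the col LEC group. The remaining splits gave at most 3, which argues against a random grouping of all 9 LEC arrays. Whether the division of pre-col from cap LEC matters for this count is not settled by these splits. Chance cannot be excluded for the single gene called off the midpoint, where 18 of 100 splits gave as many and the highest gave 5.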

How the results depend on the processing

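The alternatives for the position of pre-col LEC and the mural and fibroblast list medians without pre-col LEC replicate 1 were chosen only after the result was seen, and the other alternatives were planned. Array weights moved most counts: 792 genes between col and cap LEC, 28 between pre-col and cap LEC, 153 between col and pre-col LEC, 2 off the midpoint, 54 highest in a subtype, 321 in the overlap and a position of 0.439. After cyclic loess pre-col and cap LEC differed in 13 genes and 2 left the midpoint, as did 2 with a 75th percentile shift and 2 with trend and robust settings. With only the groups compared, col and pre-col LEC differed in 5 genes and 0 left the midpoint, also 0 with every probe set tested on its own. Stricter thresholds lowered counts by construction: with a log2 fold change of at least 1 they were 96, 23 and 998 genes for col against cap LEC, col against pre-col LEC and LEC against BEC, 0 off the midpoint, 7 highest in a subtype and 36 in the overlap, and with an adjusted p under 0.01 they were 137, 20 and 2926, and 0 off the midpoint. Leaving out 1 array gave 180 to 205 genes between col and cap LEC, 0 to 1 between pre-col and cap LEC, 24 to 47 between col and pre-col LEC, 3401 to 4410 between LEC and BEC, 0 to 2 off the midpoint, 9 to 18 highest in a subtype, 88 to 170 in the overlap, 36 to 46 list calls and a position of 0.360 to 0.419; fewer arrays lower the power. Where no construction explains a change, the cause was not tested.

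Of 46 list calls over 4 comparisons, 8 held with an estimated correlation. Cyclic loess gained 6 calls and lost 6, no filter gained 3 and lost 3, array weights gained 1 and lost 10, and leaving out pre-col LEC replicate 1 gained 4 and lost 14. The trend setting and the replicate block changed none. Of 194 calls of single named genes, 157 held under every alternative followed gene by gene, where no result reversed. These were cyclic loess, the percentile shift, trend and robust settings, array weights, the replicate block, mean or second brightest rows and leaving out arrays. Named genes were not followed through the filters, stricter thresholds, single probe sets or only the groups compared. That last fit called 5 genes between col and pre-col LEC, so at most 5 of the 14 calls kept there can have held in it.

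With the replicate block the counts were 374, 3, 72 and 4456 genes for col against cap, pre-col against cap, col against pre-col LEC and LEC against BEC, 2 off the midpoint, 19 highest in a subtype and 187 in the overlap. The labels do not say that numbers pair arrays, but sex-linked genes went with the number in every group. Xist was at 5.30 to 5.64 on replicate 2 and at 10.4 to 11.5 on replicates 1 and 3. The main fit left that difference in the spread within groups. Same-numbered arrays of different groups had deviations correlated at -0.0935 to 0.208 over 18 pairs, 7 above 0.1, and 9 of 12 arrays correlated best with their own number (exact permutation p = 0.0139 over 216 renumberings), a hint from the data and not from the design. The position was not run with the block, and fitting only the groups compared does not apply to LEC against BEC, which uses all groups. As a measure of signal over background, positive controls lay above negative controls with an area under the curve of 0.861 to 0.897 per array; which results this limits was not tested.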

Other observations

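The values printed here were chosen only after the result was seen, although the test of LEC against BEC behind some of them was planned. Several genes not described so far differed between LEC and BEC arrays by limma. Higher in LEC were Egln3, an oxygen sensor enzyme (2.20 ± 0.09, SE), Dtx1, a Notch regulator (2.12 ± 0.08), Thy1 (1.72 ± 0.12), the integrin gene Itgav (1.51 ± 0.10) and the transcription factor gene Nfatc1 (1.30 ± 0.07). Lower in LEC were the matrix genes Mgp (-3.73 ± 0.21) and Col15a1 (-3.54 ± 0.10), the guidance ligand gene Sema3g (-2.27 ± 0.15), the junction gene Jam3 (-2.24 ± 0.16) and the Notch modifier gene Mfng (-2.20 ± 0.14). The 9 LEC and 3 BEC arrays gave adjusted p values between 3.41e-10 and 6e-07 for these 10 genes. Mural markers were high in BEC too, and whether mural material raised the genes lower in LEC was not tested.

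Among the genes raised in col LEC, Slco2a1 was at 9.66 ± 0.37 in col LEC, 7.31 ± 0.11 in cap LEC and 9.75 ± 0.13 in BEC (SD, n = 3), and Nos3 at 9.99, 8.61 and 10.45 in the same groups. Adm was at 12.35, 10.57 and 10.78, and Foxp2 at 8.88, 7.89 and 6.0.

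Arrays with the same number resembled each other in sex-linked genes. Xist was at 5.30 to 5.64 on replicate 2 of every group and at 10.4 to 11.5 on replicates 1 and 3. Kdm5d was at 7.13 to 7.66 on replicate 2, against 5.64 to 6.48 on the others, and Eif2s3y at 7.37 to 7.78, against 5.97 to 6.75. Each group therefore holds the same mix on these genes, and no comparison between groups was split by them.

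Fibroblast and mural markers were highest on replicate 1 in more than 1 LEC group. The fibroblast list had a mean of 8.24 on pre-col LEC replicate 1, 7.51 on col LEC replicate 1 and 7.27 on cap LEC replicate 1, against 6.93 to 7.20 on the other LEC arrays. Rgs5 was at 8.75 on cap LEC replicate 1, against 6.67 and 7.04 on replicates 2 and 3, but in col LEC it was highest on replicate 2, at 8.15, against 6.95 and 6.90 on replicates 1 and 3.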
